A study of Mus musculus with 6 samples.

How the data were processed

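Hepatocytes of male C57BL/6J mice were profiled by mRNA sequencing, with 3 libraries from mice on a low-fat diet (LFD, 10% of energy from fat) and 3 from mice on a high-fat diet (HFD, 60% fat). Per the labels' protocols, the mice received chow with 13.5% fat until 8 weeks of age and then either diet for 12 weeks. The libraries were stranded and sequenced as paired ends, per the labels' protocols. Groups were taken from the library titles.

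Reads were checked with FastQC and aligned with STAR to mm10, per the submitters' processing notes, and the versions are not given in the sources used here. Splicing was quantified by a pair of programs. Per the file headers, the first set of tables came from voila, the viewer of MAJIQ. MAJIQ describes a local splicing variation (LSV), which is a reference exon with all junctions, and any retained intron, that leave or enter it. For each junction it gives PSI, the fraction of the variation's reads that use the junction, as a posterior mean between 0 and 1. The authors deposited a table of PSI and posterior variance for each diet, with the libraries of a diet pooled into 1 value per junction. A further table deposited by the authors lists LSVs that differed between diets, with PSI per diet, the difference in PSI (dPSI, HFD minus LFD) and a probability. Per the file headers, this dPSI table came from a separate run whose folder name marks it as strict, and what was stricter is not given in the sources used here. Per the file headers, JUM gave the last table, which lists events with a p-value under 0.05 together with an adjusted p-value and the change in PSI. Its title line names NC livers as the comparison, a short form the labels' protocols use for normal chow, while its change column is headed HFD minus LFD, and the column heading was followed here. Read minimums and the full set of events JUM tested are not given in the sources used here.

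No table used here has values per library, so no spread between animals, replicate test or paired test could be computed, and read depth per library is unknown. Posterior variances cover reads within the pooled libraries, not animals. An effective read number per junction, PSI × (1 − PSI) / variance − 1, was used to compare the precision of the diets at junctions with PSI from 0.1 to 0.9 in both.

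The comparisons and the rule for named genes were fixed before the data were examined. The plan for the dPSI table was to count LSVs with a listed probability of at least 0.95 at their largest change. That column contradicts its heading: all 205 junctions with a change under 0.2 have a probability of at least 0.95, and 13 of 214 junctions with a larger change, all 13 of them negative, have a lower one. The count reported is therefore all 124 listed LSVs, each with a change of at least 0.2. The plan as written gives 120 LSVs. It leaves out the LSVs of Mup-ps19 and Tcp1 and an LSV each of Serpina1b and Serpina1c.

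From the PSI tables, a junction was called different when PSI differed by at least 0.2 and by over 1.96 times the root of the summed posterior variances, in LSVs present for both diets. JUM events were counted at an adjusted p-value under 0.05. Overlap of the callers, membership in 12 gene lists and shares of splicing classes were compared by two-sided Fisher's exact tests, with genes or LSVs present for both diets as background (27 of the 124 listed LSVs are outside it) and Benjamini-Hochberg adjustment over lists or over classes. Each list's median of the largest PSI difference per gene was placed among 10000 random lists matched on number of LSVs and posterior variance. The median difference of retained introns was placed among 10000 draws of spliced junctions matched on mean PSI. Genes, junctions and LSVs are not replicates, so these tests describe the tables, not the animals. Bounds of shares are exact binomial with 95% confidence.

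Genes named by rule were the 15 with the largest change in the dPSI table, the 15 with the largest change among JUM events past the adjusted p-value, genes in both of these tables, changed members of the lists, and 5 genes per direction from the PSI tables with a posterior SD under 0.05. Some genes that the rule names are not reported here. Other genes are marked in the text as chosen after their values were seen.

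Some rules were settled only after results were seen. The boundary of 200 bp between shorter and longer introns was set after seeing that no listed JUM intron lies between 164 and 223 bp. A lost or gained entry of an LSV had a PSI of at least 0.2 on 1 diet and at most 0.03 on the other. This definition was also set afterwards, and it takes in spliced junctions, retained introns and entries without length. Multi-copy families were defined by a hand-written list of gene symbols, drawn up after the data were seen, and by overlap with those genes. That rule was revised 3 times after its results were seen, and the tests under each version tried are given with the closing observations. The version used takes same-strand overlap and adds the antisense transcript B430119L08Rik by name. A version with overlap on either strand also took in Brd2 and was dropped for that reason.

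Junctions were placed on GENCODE M21 (GRCm38, the assembly of mm10), with coordinates counted from 1. Flags for unannotated junctions are 0 throughout the MAJIQ tables, so leaving out LSVs with such junctions, as planned, moves nothing. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The PSI rule was tested on simulated data built from 68110 junctions. It called 0 of 50 junctions changed by 0.1, 27 of 50 changed by 0.2, 47 of 50 changed by 0.3 and 50 of 50 changed by 0.4, with 2 of 67910 unchanged junctions called. Both diets were drawn with the posterior variances that the rule itself uses and without a spread between animals. The simulation therefore gives no rate of false calls between mice. The list test called 0 of 100 lists without an effect, which were random genes whose simulated change did not depend on their number of LSVs. Alternatives covered size and probability thresholds, posterior filters, the unit counted and the table used.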

Results

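Alternative splicing was compared between hepatocytes of mice fed a high-fat diet and of mice fed a low-fat diet, with 3 libraries per diet. All values used here were pooled per diet or came from the authors' comparison, with none per library. No value below is therefore given with a spread between animals. How the authors' JUM p-values treat variation between libraries was not examined here. The LFD table held 32268 LSVs in 7095 genes, and there were 27441 LSVs in 6117 genes for HFD. The diets shared 26910 LSVs with 68110 junctions in 5978 genes. Read depth per library was unknown. At 7126 junctions of intermediate PSI, the median posterior SD was 0.0286 for LFD and 0.0321 for HFD, and the posterior variance was larger for HFD at 81.3% of them. The effective read number behind these values was 220 for LFD and 169 for HFD, a ratio of 0.768. HFD values were thus the less precise. Across junctions, which are not independent replicates, PSI correlated between diets with r = 0.996.

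The first comparison asked which splicing choices differed between the diets by MAJIQ. Outside the multi-copy gene families, the largest changes lay in Srsf1 and Srsf2, which encode SR-family splicing factors, in Apob, the structural protein of very-low-density lipoprotein, and in Tcp1, a subunit of the cytosolic chaperonin. In Srsf1 (chromosome 11), the authors' deposited table gave the annotated 3' UTR junction 88050096 to 88050976 a PSI of 0.257 on LFD and 0.992 on HFD. The PSI tables gave the same junction 0.257 and 0.462, a smaller rise. In Srsf2 (chromosome 11), the 3' UTR junction 116850354 to 116850855 rose from 0.563 to 0.998 in the authors' deposited table. In Apob (chromosome 12), an unannotated intron segment of 126 bp in the coding region, 8015566 to 8015691, went from 0 to 0.718 in the authors' deposited table and from 0.0125 to 0.704 in the PSI tables. JUM listed the intron from 8015083 to 8015691, which contains that segment, with a change of -0.00182 and an adjusted p of 0.119 in the authors' deposited table. In Tcp1 (chromosome 17), the coding junction 12923694 to 12924259 fell from 0.989 to 0.477 in the authors' deposited table.

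Altogether the authors' deposited table listed 124 LSVs in 104 genes, with the largest change positive in 70 and negative in 54. Changes of at least 0.5 were listed for 14 LSVs in the authors' deposited table. Zc3h7a, a zinc-finger gene, fell from 0.452 to 0.046 at an unannotated 30-bp junction in the authors' deposited table. The only other entry of that LSV is the same 30 bp as a retained intron, at 0.548 and 0.954. Eva1a is listed at 0.434 and 0 in the authors' deposited table for an entry of length 0 that is not a splice junction. Its annotated 5' UTR junction of 29153 bp went from 0.347 to 0.739 in the authors' deposited table, against 0.615 and 0.735 in the PSI tables and a JUM change of 0.0569. Of the listed LSVs, 92 had their largest junction in both PSI tables, where 78 differed by over 0.2 in the same direction, 80 lay within 0.1 of the listed value and 3 had the opposite sign.

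Multi-copy families held 24 of the 124 LSVs and 10 of the 14 largest changes. Near-identical copies can share reads, so the values of these genes are uncertain. Serpina1 genes encode alpha-1-antitrypsin, Mup genes the major urinary proteins and Hamp2 a hepcidin. The authors' deposited table gave 0.007 and 0.997 for a Serpina3m junction, 0.049 and 0.998 for Serpina1b, and 0.05 and 0.997 for Gm8893 at the same coordinates as Serpina1b. In the authors' deposited table Mup10 rose from 0.357 to 0.996, Mup17 from 0.27 to 0.817 and Hamp2 from 0.429 to 0.987, while Mup-ps19 fell from 0.967 to 0.175. Serpina1c fell from 0.919 to 0.002 in the authors' deposited table, yet the PSI tables gave 0.902 and 0.952 for that junction. For the antisense transcript B430119L08Rik the authors' deposited table gave 0.089 and 0.998, against 0.0954 and 0.0413 in the PSI tables.

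**Figure D1:**
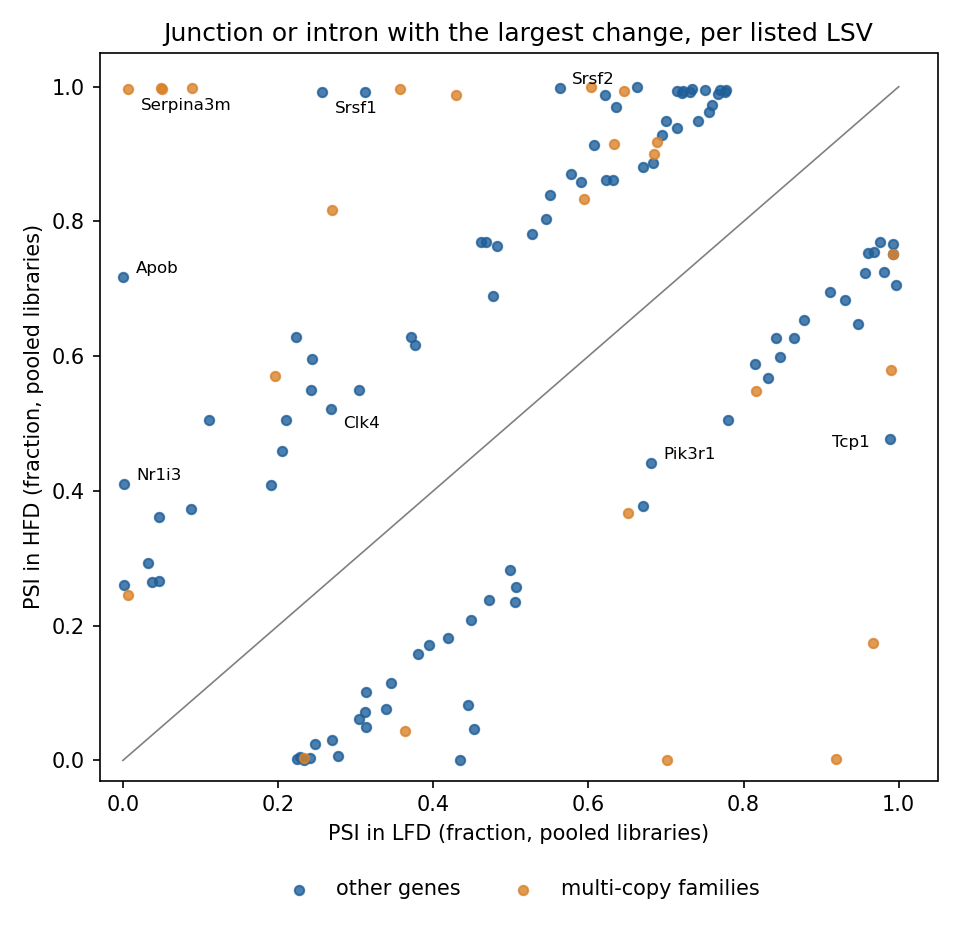
PSI on LFD (horizontal axis, fraction) against PSI on HFD (vertical axis, fraction) for the most changed junction of each of the 124 LSVs in the authors' deposited table, 1 point per LSV and without error bars, with multi-copy families in orange. Of the 14 LSVs with a change of at least 0.5, 10 belong to these families.

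Among the gene lists, splicing factors passed the test in the dPSI table, with 6 of 81 measured members listed (odds ratio 4.78, adjusted p = 0.031, Fisher's exact test). The members were Srsf1, Srsf2, Clk4, Hnrnph3, Luc7l2 and Sfpq. Clk4, a kinase of SR proteins, rose from 0.268 to 0.521 at a junction of 833 bp in the authors' deposited table. The junction that skips an exon of Hnrnph3 rose from 0.304 to 0.55 in the authors' deposited table. Luc7l2 rose from 0.635 to 0.97 in the authors' deposited table and from 0.86 to 0.972 in the PSI tables. Its LSV in the authors' deposited table also holds an entry without length, which is not a splice junction. That entry fell from 0.288 to 0.002, so the listed rise of Luc7l2 is in part its counterpart. In an LSV assigned to Sfpq, which encodes a paraspeckle protein, a 282-bp intron fell from 0.25 to 0.005 in the authors' deposited table. That intron is annotated only in processed transcripts and lies outside the coding transcripts of Sfpq. The same intron is also listed under Gm12940, at 0.241 and 0.003 in the authors' deposited table. The list also passed with genes past the PSI rule (7 of 81, odds ratio 4.16, adjusted p = 0.0302) but not with only the listed genes that recurred in the PSI tables (4 of 81, odds ratio 4.73, adjusted p = 0.159), by Fisher's exact test. None of the 81 passed in the JUM table, where 0.854 were expected, and the list's median largest PSI difference lay at percentile 54.3 of matched random lists. That median was 0.0691, against 0.0686 in the matched lists. The Fisher's exact tests were not matched on number of LSVs or posterior variance, so the odds ratios cannot be separated from these properties.

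The metabolic lists did not pass the test. Listed members made up from 1.49% (mitochondria) to 2.5% (lipid metabolism) of those measured, against 1.72% of all background genes. Lipid metabolism had 2 of 80 members listed, Apob and the lipid-droplet gene Cidec, whose 83-bp intron fell from 0.23 to 0.005 in the authors' deposited table (adjusted p of the list = 1). Of 52 cholesterol and bile acid genes, 1 was listed. Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, was the listed member among 58 insulin and glucose genes and fell from 0.681 to 0.441 at a junction of 10863 bp in the authors' deposited table. Among 81 xenobiotic and nuclear receptor genes, Nr1i3, which encodes the receptor CAR, rose from 0.001 to 0.41 at a 69-bp intron segment in the authors' deposited table. Cyp3a25, from a multi-copy family, fell from 0.99 to 0.579 in the authors' deposited table. Polg, the mitochondrial DNA polymerase, fell from 0.968 to 0.754 in the authors' deposited table, as the listed member among 67 mitochondrial genes. Stat2, a transcription factor of interferon signalling, was listed among 74 stress and inflammation genes, and its 72-bp intron fell from 0.27 to 0.03 in the authors' deposited table. Another Stat2 intron, 128281771 to 128282101 on chromosome 10, went the other way, from 0.081 to 0.236 in the authors' deposited table. None of the 28 epithelial exon genes was listed, nor any of the 7 macrophage, 7 endothelial, 4 stellate and 3 bile duct markers measured. In the PSI tables the endothelial marker Nrp1 passed the PSI rule, with 0.498 on LFD and 0.255 on HFD, as did the epithelial exon gene Arhgef11, with 0.525 and 0.811. Both were named after their values were seen.

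The second comparison used JUM, which asks the same question with other event definitions. Retained introns were mostly higher on HFD: 42 of the 43 retained introns past the adjusted p were higher, in 31 of 32 genes. The median change of these introns in the authors' deposited table was 0.148, and the rises ranged from 0.0285 to 0.343. Fh1, the fumarate hydratase of the citric acid cycle, rose by 0.343 at a 1820-bp intron in the authors' deposited table (adjusted p = 4.1e-04). In the same authors' deposited table the rise was 0.331 in Itih1, 0.321 in Fdx1, an electron donor to mitochondrial P450 enzymes, 0.275 in the autophagy gene Vmp1 and 0.25 in Retreg1. The phosphatidate phosphatase gene Lpin2 had 5 retained introns in the authors' deposited table, all higher on HFD, 3 of them past the adjusted p, with a largest rise of 0.264. Tcp1 likewise had 5 in the authors' deposited table, all higher, 2 past the adjusted p, with a largest rise of 0.251. Rises in the authors' deposited table were 0.228 in the histone gene H3f3b, 0.222 in Ifrd1, 0.209 in the polyamine acetyltransferase gene Sat1 and 0.207 in the thiamine transporter gene Slc19a2. Errfi1, named after its value was seen, was the exception and fell by 0.0737 in the authors' deposited table.

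Direction differed with intron length. Of 118 retained introns listed at any adjusted p, 98 were higher on HFD, and 108 matched an annotated intron. Introns of at most 200 bp were higher on HFD in 16 of 31 cases with 0 past the adjusted p, and longer introns in 82 of 87 cases with 43 past it. The difference had a p of 5.8e-07 at this boundary, set after the data were seen, and 0.135 at 500 bp (Fisher's exact test). The JUM table holds only events with a p under 0.05, so these counts describe a selected set.

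**Figure D2:**
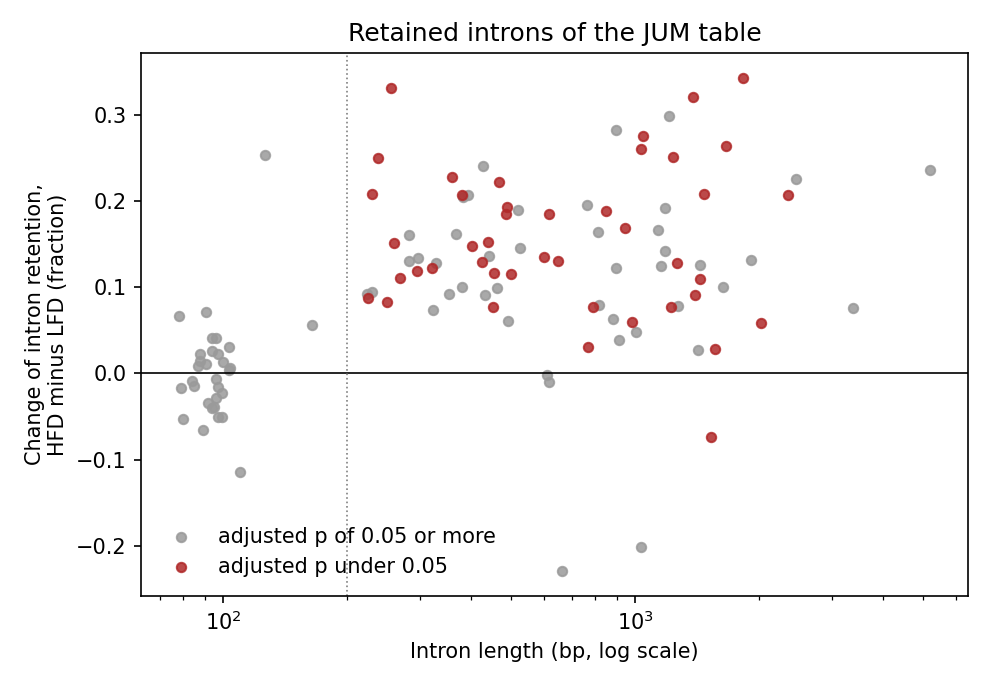
Length of each of the 118 retained introns in the authors' deposited JUM table (horizontal axis, bp, log scale) against its change in PSI, HFD minus LFD (vertical axis), 1 point per intron and without error bars, in red where the adjusted p was under 0.05. Introns past the adjusted p are all longer than 200 bp, and 42 of the 43 lie above 0.

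In all, 83 of 470 JUM events in 68 genes passed the adjusted p. Besides the introns they were 13 alternative 5' splice sites, 9 alternative 3' splice sites, 6 cassette exons and 12 composite events. The largest change in the authors' deposited table, 0.694, was a 771-bp junction of Gm21320 on chromosome 4 (adjusted p = 2.7e-90). It lies within the annotated gene Mup22 of the multi-copy Mup family, so its value is uncertain. Eif4g3, a translation initiation factor, rose by 0.41 at a 37474-bp junction in the authors' deposited table. No list passed the test in the JUM table. Xenobiotic genes came nearest, with 4 of 81 members (adjusted p = 0.122, Fisher's exact test). These were Cyp2c68, at -0.0772 in the authors' deposited table, Cyp2d10 at -0.0133, Ugt1a6b at -0.0479 and Ces3a at 0.00517, all from multi-copy families and uncertain for that reason. Of 80 lipid genes, Lpin2, Scd1 and Cyp4a12a passed, and the stearoyl-CoA desaturase gene Scd1 rose by 0.0586 at an intron in the authors' deposited table. The exon change of Cyp4a12a, also from a multi-copy family, was 0.0241 in the authors' deposited table. Of 74 stress and inflammation genes 3 passed, among them Itih1 and Hp, the latter with 0.00163 in the authors' deposited table. Of the mitochondrial genes, Fh1 and Slc25a47 passed, the latter with 0.123 at an intron in the authors' deposited table. Of 58 insulin and glucose genes 1 passed. Ndrg2, at -0.193 for a 5' UTR junction in the authors' deposited table, was the member from the epithelial list.

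The third comparison set the callers side by side. Atp13a1, Kif21a, Rbm4, Tcp1, Txnrd1 and Vmp1 changed in both tables, 6 genes against 1.09 expected by chance (odds ratio 6.31, Fisher's exact test p = 6.9e-04). In the RNA-binding protein gene Rbm4, the 5' UTR junction 4792821 to 4793815 on chromosome 19 rose from 0.482 to 0.763 by MAJIQ in the authors' deposited table, and JUM listed the competing junction at -0.383. In Atp13a1, the coding junction 69799479 to 69799761 on chromosome 8 fell from 0.947 to 0.648 by MAJIQ and by 0.285 by JUM in the authors' deposited table. The junction that skips a 129-bp exon of the kinesin gene Kif21a rose from 0.591 to 0.859 in the authors' deposited table, where JUM gave the exon -0.163. In the thioredoxin reductase gene Txnrd1, the junction into a 107-bp 5' UTR exon rose from 0.527 to 0.781 in the authors' deposited table, where JUM gave the exon 0.0673. For Vmp1 and Tcp1 the callers listed different introns, higher on HFD in each. Both callers used the same libraries, so the overlap is not independent evidence. With a JUM adjusted p of 0.01 the odds ratio was 3.73 (Fisher's exact test p = 0.110).

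At 417 spliced junctions found by coordinates in both the JUM and PSI tables, the change had the same sign at 349 and the opposite sign at 9, while 59 differed by under 0.0001 in the PSI tables, and r was 0.927 across junctions, which are not independent replicates. Where the JUM change was at least 0.1, 137 of 139 junctions had the same sign. For cassette exons the skipping junction was compared, with the sign of the JUM change reversed. For retained introns only 23 could be matched, with the same sign at 10, the opposite sign at 3, a difference under that limit at 10 and r = 0.424. Where the JUM change was at least 0.1, 4 of 5 introns had the same sign. The limit of 0.0001 was set after the counts were seen. Over 6 limits from 0 to 0.01 the same sign was found at 326 to 372 spliced junctions and 8 to 15 introns, and the opposite sign at 5 to 14 and 2 to 3.

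**Figure D3:**
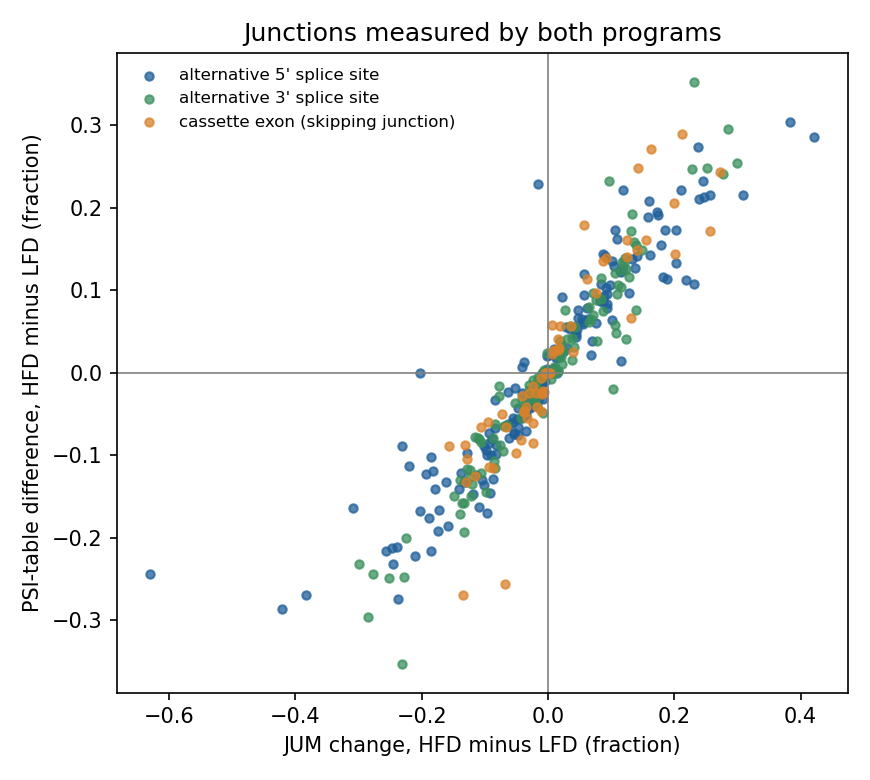
Change in PSI, HFD minus LFD, in the authors' deposited JUM table (horizontal axis) against the difference between the PSI tables at the same spliced junction (vertical axis). There is 1 point per junction, without error bars. For a cassette exon the point is its skipping junction, and the sign of the JUM change of the exon is reversed. The sign was the same at 349 and opposite at 9 of 417 spliced junctions. The others differed by under 0.0001 between the PSI tables, a limit set after the counts were seen. Retained introns are not drawn.

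The PSI tables were then compared directly. The widest differences were again in the multi-copy families: Serpina3k, Serpina1a, Serpina1b, Mup3 and Hamp2 among junctions higher on HFD, and Serpina1a, Serpina1b, Mup3, Gm8893 and Mup16 among those lower. A Serpina3k junction had a PSI of 0.0127 ± 0.0021 on LFD and 0.987 ± 0.0038 on HFD (posterior SD), and a Mup16 junction 0.791 ± 0.0283 and 0.186 ± 0.0312. The rule was passed by 284 junctions of 168 LSVs in 138 genes, 143 higher and 141 lower on HFD, and 76 of the genes were also in the dPSI table. PSI values of an LSV are shares of the same reads, so a rise at a junction brings falls at others. The near-even split is therefore largely by construction. For Serpina1a, Serpina1b and Mup3, the named rise and fall are of the same size.

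Splicing classes differed between listed LSVs and all LSVs present for both diets, although 27 of the 124 listed LSVs were not among the latter. The 124 listed LSVs held 419 junctions and introns, and the 26910 present for both diets held 68110. The class tests were not matched on the number of junctions per LSV. Retained introns were part of 56.5% of listed and 25.5% of all LSVs (odds ratio 3.80, adjusted p = 1.9e-12, Fisher's exact test). Alternative 5' splice sites were part of 42.7% against 22.3% (odds ratio 2.60) and alternative 3' splice sites of 49.2% against 31.5% (odds ratio 2.11). Exon skipping was less frequent, 52.4% against 65.4% (odds ratio 0.583, adjusted p = 0.0040, Fisher's exact test). With only listed LSVs from both PSI tables, exon skipping had an odds ratio of 0.722 (adjusted p = 0.167, Fisher's exact test). Counted by genes, the odds ratios of the alternative splice sites were 0.677 and 0.543. The listed introns went both ways, with 30 higher and 26 lower by at least 0.2 in the authors' deposited table. Over all 6850 introns of the PSI tables the median difference was 0, at percentile 49.1 of matched spliced junctions. The matched median was also 0. Most of these introns had a mean PSI under 0.05, which leaves the median little room to shift. Among 2172 introns with a mean PSI of at least 0.05, the median difference was 0.00394, at percentile 100 of matched spliced junctions, and 54.2% were higher on HFD. Introns higher by at least 0.1 numbered 195 and those lower by at least 0.1 numbered 125.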

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

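Chosen after seeing the data were the alternatives on multi-copy families, recurrence or presence in the PSI tables, JUM events without introns, all settings for the share of retained introns, the overlap at a raw JUM p and the PSI-table values of named genes. The others were planned, and the listed probability of 0.95, which gives 120 LSVs, was the original rule. Of 54 alternative settings for the comparisons, 34 gave the same call, a count within 1.5 times or an untested value within its 95% bounds. Settings that leave out unannotated junctions are among the 34 and could not differ, since no such flag is set. The posterior part of the PSI rule also had next to no effect. Junctions past the rule numbered 284 with or without it and 283 at 3 posterior SDs. Of 22 named genes, 17 had a PSI-table difference that lay from the dPSI table's by less than the posterior spread of the PSI rule. The listed LSVs numbered 36 with a change of at least 0.3 and 78 when they had to recur in the PSI tables. Junctions past the PSI rule numbered 1953 at 0.1 and 65 at 0.3. JUM events numbered 44 at an adjusted p of 0.01, 470 at a raw p of 0.05, 46 with a change of at least 0.1, 20 with at least 0.2 and 40 without retained introns. These counts move by the construction of each setting. The share of retained introns higher on HFD was 83.1% at a raw p of 0.05 and 51.6% among those of at most 200 bp. The overlap of the callers had an odds ratio of 3.73 at a JUM adjusted p of 0.01, with fewer genes entering. The median intron difference was 0.00394 at a mean PSI of at least 0.05, at percentile 100 of matched junctions against 49.1 for all introns. Most of all introns had a mean PSI under 0.05, which leaves their median little room to shift.

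The number of lists past the test was 0 with the genes of the JUM table and 0 with genes changed alike in the PSI tables. Splicing factors passed with genes past the PSI rule (odds ratio 4.16, adjusted p 0.0302) and outside multi-copy families (6.05, 0.0101). These Fisher's exact tests were not matched on number of LSVs or posterior variance. For splicing factors the odds ratio was 0 with the JUM table, where 0.854 members were expected, too few to read a direction, and 4.73 with genes changed alike in the PSI tables, where the adjusted p rose to 0.159. With only listed LSVs from both PSI tables, the odds ratio of exon skipping was 0.722 and no longer passed. The cause was not tested. Counted by genes, alternative 5' splice sites had an odds ratio of 0.677 and alternative 3' splice sites 0.543, both reversed. By construction a background gene there counts any of its LSVs and a listed gene only its listed ones. Serpina1c reversed to 0.0503 and B430119L08Rik to -0.0541 in the PSI tables, and Hamp2, Luc7l2 and Srsf1 kept their direction with other sizes. For Luc7l2, the LSV of the dPSI table holds an entry without length, at 0.288 on LFD and 0.002 on HFD. Whether this entry accounts for the smaller rise in the PSI tables was not tested, nor was the cause for the other genes.

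No paired analysis was possible because no table used here has values per library. For the same reason the planned test of JUM junction usage per library was not run, nor were its alternatives with a replicate block, with each library left out, with other models or normalizations, or with a count minimum. Unknown read depth leaves the lower precision on HFD as the only measure of depth.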

Other observations

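The Fisher's exact tests, shares and intron medians reported in this part were chosen only after the results they bear on had been seen, and so were the genes named here, while the PSI rule and the JUM threshold were planned.

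The PSI rule was passed by 53 genes outside the dPSI table and the multi-copy families. Of these, 3 are on the splicing-factor list. A junction of Esrp2, an epithelial splicing regulator, had a PSI of 0.887 ± 0.0312 on LFD and 0.676 ± 0.0435 on HFD (posterior SD). Junctions of Rbm25 (0.259 and 0.485) and Prpf38b (0.14 and 0.351) were higher on HFD. The growth hormone receptor gene Ghr had a junction at 0.276 ± 0.0331 on LFD and 0.0608 ± 0.0204 on HFD. Junctions of the chromatin gene Ctcf (0.0855 and 0.287), of the interferon factor gene Irf9 (0.252 and 0.467) and of the endothelial marker Nrp1 (0.498 and 0.255) also passed. The ubiquitin-conjugating enzyme gene Ube2d3 had a 5' UTR junction at 0.392 on LFD and 0.6 on HFD, and JUM gave it 0.160 with an adjusted p of 0.0251 in the authors' deposited table.

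Several genes were listed at the same junction by both callers but missed the adjusted p in JUM. The clock gene Arntl rose from 0.577 to 0.87 at the junction 113295594 to 113299186 on chromosome 7, and JUM gave 0.299 with an adjusted p of 0.223 in the authors' deposited table. For Uhrf1bp1l the authors' deposited table gave 0.714 and 0.993 by MAJIQ and 0.238 by JUM (adjusted p = 0.339). An LSV was listed for 1065 genes on LFD only and for 87 on HFD only. An LSV listed on a single diet is not evidence of expression there alone.

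In the JUM table, where retained introns were mostly higher on HFD, few long introns could be matched in MAJIQ and only selected events are listed. More unspliced RNA or DNA throughout the HFD libraries would raise short introns too, but 51.6% of listed introns of at most 200 bp were higher (bounds 33.1% to 69.8%) against 94.3% of longer ones. This explanation stays open, because those introns were selected by p and the 2095 such introns of the PSI tables with a mean PSI of at least 0.05 had a median difference of 0.0042, at percentile 100 of matched spliced junctions. A few genes with several introns do not account for it, since 96.9% of genes were higher with 1 value per gene (lower bound 83.8%). Direction differed by length at the 200-bp boundary (Fisher's exact test p = 5.8e-07) and boundaries of 100, 150 and 300 bp gave p of 1.7e-07, 3.1e-07 and 2.4e-04, but 500 bp gave 0.135, so handling of introns by length in the caller and a diet effect on longer introns cannot be told apart, since each would give this split.

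The largest changes lay in multi-copy families. The PSI tables came from another run. There 20 of 23 differences of at least 0.5 were in families, against 38 of 261 smaller ones (Fisher's exact test p = 8.7e-13). Large changes in families were thus not confined to the separate run behind the dPSI table. The p adds no support, because the family list was written after the data were seen and junctions of the same LSV were counted separately. Reads shared between near-identical copies were not decided by the test run: changed junctions joining 2 annotated genes were found in 7 of 24 family LSVs and 0 of 100 others (Fisher's exact test p = 4.6e-06), a count that tandem gene clusters come close to fixing. The family rule was revised after its results were seen, and over the 5 versions computed the first p ranged from 8.7e-13 to 2.4e-08 and the second from 3.3e-06 to 7.6e-05. Shared reads and a diet effect on these genes both stay open.

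More LSVs lost an entry on HFD than gained one in the dPSI table, 38 against 14, or 73.1% lost. Entries here are spliced junctions, retained introns and entries without length, and introns are found among both the lost and the gained. Fewer reads in the HFD libraries would be looked for as an excess in the PSI tables too, where 33 were lost and 31 gained, or 51.6% (bounds 38.7% to 64.2%). These counts cannot decide it, because they cover only LSVs present for both diets. Another 5358 LSVs were in the LFD table only and 531 in the HFD table only. Of the 124 listed LSVs behind the 73.1%, 27 were not in both. Over 5 definitions tried, the share lost ranged from 65.6% to 73.5% in the dPSI table and from 51.2% to 55.4% in the PSI tables. Whether the choice of listed LSVs made the excess cannot be told apart from a diet effect, since 15 of 33 lost and 9 of 31 gained LSVs were listed (Fisher's exact test p = 0.205).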
